A study of Mus musculus with 9 samples.

How the data were processed

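Gene expression was measured in liver of KKAy mice, an obese strain used as a model of type 2 diabetes, on 9 one-colour Affymetrix arrays in 3 groups of 3. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, the mice were 8 weeks old, ate a chow with 34% fat and were divided into groups of 8 to 12 animals. Intraperitoneal injections of 100 µL held culture medium (DMEM) alone, insulin at 40 µg/mL, or insulin at the same total concentration of which 11% was biomineralized, again per the labels' protocols. The characteristics of the first group give its treatment as none, and it is called untreated here; the labels do not say whether these are the control mice of the protocol. The growth protocol given for 1 of the 9 arrays, BI replicate 2, describes rats, and that array was kept with its labelled group. RNA was extracted with TRIzol, purified on RNeasy columns and turned into biotin-labelled cRNA with a 3' IVT kit, per the labels' protocols.

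The deposited values are log2 signals per probe set, processed by the authors. The summarization and normalization software is not given in the sources used here. Every array had a lowest value of exactly 0 (152 to 247 probe sets per array), and the 2% trimmed mean of the linear signal was 500.004 on each array. The values were therefore taken as already scaled to one level per array, with a floor at a linear signal of 1, and were used as deposited. No background measure or detection call was used. The file held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested. Gene names came from the platform annotation of 2016: 34945 probe sets had 1 gene symbol, 932 had several and 9160 were unnamed here. Of those with 1 symbol, 34741 were matched by gene ID to a table of current names. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18193 genes.

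All 9 arrays entered one limma fit (lmFit and eBayes without trend, 6 residual degrees of freedom) with the group as the only factor. The 3 pairwise comparisons were two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05, and a moderated F test covered the 3 groups together. Gene lists, 30 of pathways and 14 of cell types, held 1001 genes of which 886 were measured. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 44 lists. Beside it, camera was run with an estimated correlation, and fry, a rotation test of whether a list moves on balance one way, was run too. Standard errors and 95% intervals come from the limma fit. The groups, the tests, the gene lists, the rule for named genes and all but 3 of the other settings named here were fixed before the data were examined.

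By the rule for named genes, each comparison names up to 10 genes past the threshold in each direction whose groups do not overlap, filled up to 5 with the genes of smallest p in that direction, which are given as values. Each list names its members past the threshold or, where none passed, the 2 of smallest p. Probe sets without a symbol and genes named only as clones or predictions were outside this rule. The name patterns used to apply it were narrowed to its wording after values were seen, which brought BC048507 under it. Genes named outside it are said to be chosen after their values were seen. Whether same-numbered arrays vary together was checked before the pairing alternative was read. Insulin and BI share the untreated arrays, so the correlation of their changes was set beside 50 simulations of unchanged groups.

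The tests were tried on simulated data in which probe sets were changed in the BI against untreated comparison of 45037 probe sets. Over 10 simulations, a 4-fold change was recovered for 350 of 621 probe sets at or above the median level (56.4%) and for 12 of 379 below it (3.17%). A 2-fold change was recovered for 0.329% and 0.510% of probe sets at these levels. False calls numbered 3.2 per simulation, and 0 per simulation in the comparison left unchanged. A list shifted by 0.5 (log2) was called in 10 of 10 simulations, with 1 other list called. Probe sets were drawn independently in these simulations. They therefore do not show how often unchanged lists are called when their genes vary together. The number of arrays limits the precision. The median 95% half-width of a log2 difference was 2.12 for probe sets with a mean level of 3 to 5, 0.58 at 7 to 9 and 0.39 at 12 to 17.

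Other settings tried were quantile normalization, equal array medians, a filter on probe sets below the median mean level of 6.04, variance moderation with a trend and robust fitting, fits of only the groups compared, array weights, the mean of a gene's probe sets, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were a floor at 6, the filter together with the trend and robust fitting, and a clock gene score as a covariate. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.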

Results

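Liver expression profiles were obtained from KKAy mice, an obese mouse model of type 2 diabetes. The mice were untreated, injected with insulin, or injected with insulin of which 11% was modified by biomineralization in place (BI). Each group had 3 arrays. The labels give the treatment of the first group as none, while the protocol describes control mice injected with medium, so it is not known whether comparisons with this group include an effect of the injection itself. The labels do not say whether an array came from 1 animal or a pool, so the p-values measure only the spread between these samples, which may be technical. Array medians lay between 6.12 and 6.30 on the log2 scale. Y-linked Eif2s3y (11.57 to 11.90), Kdm5d (8.45 to 9.32) and Uty (8.88 to 9.63) were well above the array median on each of the 9 arrays, and Xist, the transcript that silences an X chromosome in females, lay between 5.54 and 6.96. The 3' minus 5' difference of Gapdh, a sign of RNA quality, was 0.41 ± 0.20 in the untreated group, 0.52 ± 0.04 with insulin and 0.36 ± 0.08 with BI (log2, mean ± SD, n = 3), and was highest of the 9 arrays on untreated replicate 3 (0.65, against 0.28 and 0.31 on the other 2 untreated arrays). Arrays of one group correlated at r = 0.911 to 0.920 and arrays of different groups at r = 0.909 to 0.921. Changes below are log2 differences ± SE from the limma fit, with 3 arrays per group.

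Insulin was compared with no treatment to ask how the liver of these mice responds to the injected hormone. No single gene passed the threshold. The genes with the smallest p included BC048507 (+2.97 ± 0.28, from a level of 1.13 to 4.10) and Eomes, a transcription factor of natural killer and T cells (+2.65 ± 0.25), both with an adjusted p of 0.171 and both higher in 3 of 3 insulin arrays than in any untreated array. Gpr31b, a G protein-coupled receptor (+2.88 ± 0.34), Paqr6, a membrane progestin receptor (+2.38 ± 0.33), and Ano4, a member of the anoctamin family (+1.84 ± 0.26), followed among the higher genes. The lower ones were Cabp1, a calcium-binding protein of neurons (-3.15 ± 0.38, adjusted p 0.291), Nxph1, a secreted neuronal ligand (95% interval -4.11 to -1.89), Fhad1 (-2.17 ± 0.35), Il23a, a subunit of interleukin 23 (-3.61 ± 0.64), and Rnf39 (-2.09 ± 0.39). The group means of these 10 genes lay below the lowest array median (6.12). limma called 0 of 45037 probe sets (smallest adjusted p 0.171), while 2014 (4.47%) had an unadjusted p under 0.05, where chance gives 5%. The groups did not overlap for 9.19% of probe sets, where chance gives 10%.

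With insulin, 6 lists passed in the test with a preset correlation between genes and none passed with an estimated one. In cholesterol synthesis 19 of 20 measured genes were lower (median -0.51), among them Msmo1, which removes a methyl group from sterol intermediates (-1.36 ± 0.46), and Dhcr7, the enzyme of the last step to cholesterol (-0.76 ± 0.34). The adjusted p was 1.7e-07 with the preset correlation, and adjusted p = 0.996 with an estimated correlation. Of the interferon-response genes 28 of 29 were higher (median 0.68, adjusted p 1.7e-07, and adjusted p = 0.996 with an estimated correlation), such as the interferon-induced Oasl2 (+1.66 ± 0.48) and the GTPase Igtp (+0.94 ± 0.32). MHC class II genes, which present antigen to T cells, were higher in 8 of 9 cases (median 0.45, adjusted p 0.00146, and adjusted p = 0.996 with an estimated correlation), including H2-Aa (+0.79 ± 0.26) and the peptide-loading gene H2-DMa (+0.81 ± 0.29), which stood at -0.53 when its probe sets were averaged. Of the endothelial cell markers 18 of 20 were higher (median 0.29, adjusted p 0.00696, and adjusted p = 0.996 with an estimated correlation), with Emcn at +0.58 ± 0.32 and Lyve1, the hyaluronan receptor of sinusoids, at +0.96 ± 0.60. The endothelial score overlapped too, with insulin replicate 3 (-0.02) below untreated replicate 3 (0.38). Kupffer cell and macrophage markers had a median of 0.28 that did not pass (adjusted p 0.173), with the macrophage marker Adgre1 at +0.46 ± 0.20 and the monocyte chemokine receptor Ccr2 at -0.54 ± 0.19.

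Lipogenesis genes were lower in 22 of 28 cases with insulin (median -0.21, adjusted p 0.00693, and adjusted p = 0.996 with an estimated correlation). Acacb, which makes the malonyl-CoA that restrains fatty acid oxidation, stood at -1.26 ± 0.71, and Srebf1, the transcription factor that drives lipogenesis, went the other way at +0.29 ± 0.16. Amino acid and urea metabolism was lower in 23 of 26 genes by a small amount (median -0.11, adjusted p 0.00446, and adjusted p = 0.996 with an estimated correlation), among them the tyrosine-degrading enzymes Tat (-0.30 ± 0.19) and Fah (-0.25 ± 0.17). The groups did not overlap in the scores per array of MHC class II and amino acid metabolism, and overlapped in those of the other lists called. No member of any list passed over all probe sets or adjusted over the list alone, and fry called 0 of 44 lists (smallest adjusted p 0.994).

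Several of these calls were lost, or their medians moved, when 1 array was left out. Without untreated replicate 3, the array with the highest Gapdh difference, the median of cholesterol synthesis was -0.18 (adjusted p 0.0178) and that of lipogenesis -0.015 (0.813). Whether RNA quality bears on these lists was not tested. Lipogenesis also lost its call without insulin replicate 3 (median -0.087, adjusted p 0.549) and moved to -0.37 without untreated replicate 1. The interferon median was 1.03 without insulin replicate 1 and 0.44 without insulin replicate 2 (adjusted p 0.0102). Without insulin replicate 3, MHC class II had a median of 0.24 (adjusted p 0.140) and amino acid metabolism one of -0.076 (0.184), while without insulin replicate 1 the latter's median was -0.17. The endothelial markers lost their call without untreated replicate 1 (median 0.12, adjusted p 0.555), insulin replicate 1 (0.20, 0.308) or insulin replicate 2 (0.24, 0.0970) and had a median of 0.49 without untreated replicate 3.

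The other 38 lists did not pass with insulin (adjusted p 0.120 to 0.996). The insulin signalling list, 27 genes of the receptor pathway, had a median of 0.02, while its mean was -0.0017 and its test pointed lower (adjusted p 0.970). The kinase Akt1 stood at -0.55 ± 0.22 and Gsk3a, which restrains glycogen synthesis, at +0.36 ± 0.17. Among gluconeogenesis genes and targets of FOXO1 (median -0.03, adjusted p 0.568) the coactivator Ppargc1a stood at -0.57 ± 0.20 and the nuclear receptor Nr4a1 at +0.33 ± 0.19. Histone and DNA modifying enzymes, to which the study's title points, had a median of 0.06 over 51 genes, a mean of -0.0026 and an adjusted p of 0.996, with Tet1, which oxidizes methylated cytosine, at -1.79 ± 0.83 and the histone deacetylase Hdac4 at +0.40 ± 0.20.

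**Figure D1:**
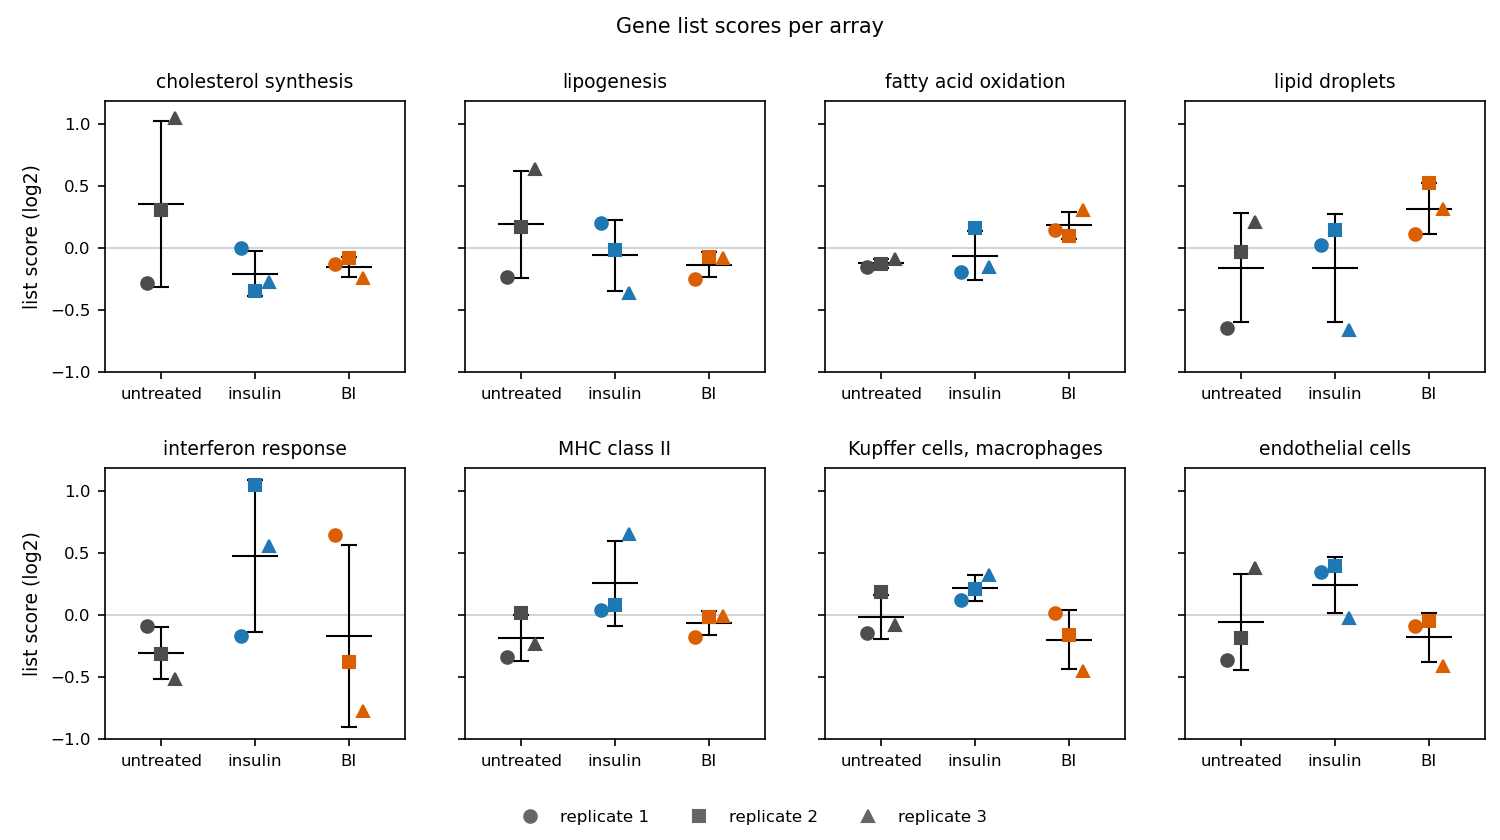
Gene list scores per array (vertical axis, log2; mean over the members of each list of the value minus its mean over the 9 arrays) for untreated, insulin and BI groups, with group mean and SD as bars and a symbol for each replicate number. The cholesterol synthesis score was highest on untreated replicate 3 (1.05), and the interferon score on insulin replicate 2 (1.04), followed by BI replicate 1 (0.64) and insulin replicate 3 (0.55). The cholesterol synthesis score of untreated replicate 1 (-0.28) lay below every BI array and between insulin replicates 3 (-0.27) and 2 (-0.35).

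BI was compared with no treatment to ask how the liver responds to the injected mixture. As 11% of its insulin was biomineralized, this comparison does not separate a response to that form from one to the rest of the insulin. Of the 5 probe sets that passed, 3 were higher with BI and 2 lower. A probe set of Slc6a14, a transporter of neutral and basic amino acids, was at or near the floor of 0 on the untreated arrays (highest 0.037) and at 4.15 ± 0.22 with BI (mean ± SD, n = 3, limma adjusted p 0.0384). Cdhr2, a protocadherin of the microvilli of epithelial cells, fell from 5.85 to 1.90 (-3.94 ± 0.34, adjusted p 0.0452). BC048507 rose from 1.13 to 4.42 (+3.29 ± 0.28, adjusted p 0.0452), and a probe set without a gene name here rose from 2.57 to 5.49 (+2.92 ± 0.21, adjusted p 0.0384). A probe set of Hnrnpl, an RNA-binding regulator of splicing, fell from 7.28 to 4.32 (-2.95 ± 0.23, adjusted p 0.0384), while the brighter probe set of the same gene was at -0.04 (95% interval -0.48 to 0.39). The other Slc6a14 probe set was at -0.53 (95% interval -2.70 to 1.63). Apart from Hnrnpl without treatment and with insulin (6.77), the group means of the 5 probe sets lay below the lowest array median (6.12), and with no background measure it is not known whether those signals were above background. In all 5 the BI arrays lay on one side of the untreated ones in 3 of 3 cases. Slc6a14, Hnrnpl and the unnamed probe set fall outside the rule for named genes and were chosen after their values were seen.

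**Figure D2:**
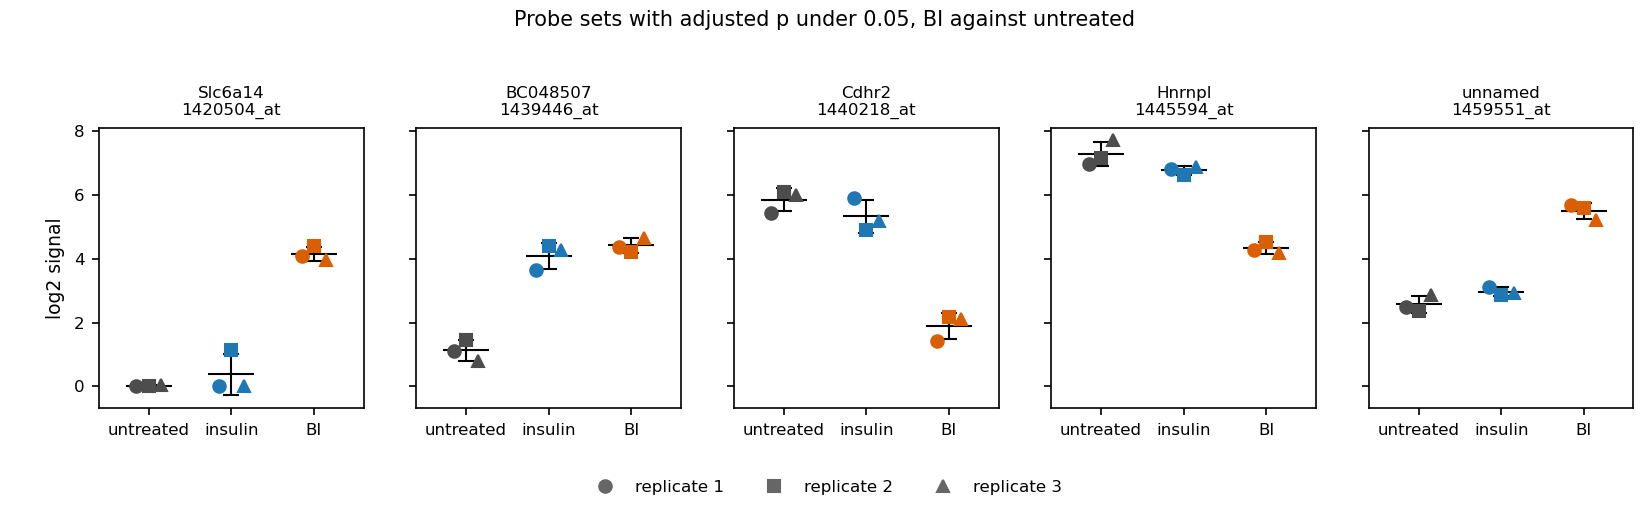
Log2 signal (vertical axis) of the 5 probe sets with an adjusted p under 0.05 in BI against untreated, in the 3 groups, with group mean and SD as bars and a symbol for each replicate number. The Slc6a14 probe set lies at 0 to 0.037 on untreated arrays and near 4.15 with BI, and the Hnrnpl probe set falls from a mean of 7.28 to 4.32.

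The 5 probe sets were lost as calls when any 1 of the 6 untreated or BI arrays was left out (0 called, smallest adjusted p 0.0730 to 0.153), and also without insulin replicate 1 or 3. Without insulin replicate 2, 2 were called, of which 1 was shared. Leaving out dim probe sets took all of the 5 but Hnrnpl out of the test by their level, and Hnrnpl was the 1 probe set called. With a variance trend and robust fitting together 6 passed, of which 1 was shared. Among those 6 were Cyp2c39 (+1.28 ± 0.21) and Cyp2c38 (+1.61 ± 0.28), cytochrome P450 enzymes, Moxd1, a copper-dependent monooxygenase (-1.08 ± 0.22), and the semaphorin receptor Plxnb1 (-1.30 ± 0.19), each with an adjusted p of 0.0493 there. In the test used throughout they did not pass, with adjusted p of 0.503 (Cyp2c39), 0.563 (Cyp2c38), 0.627 (Moxd1) and 0.480 (Plxnb1). Further genes filled in by the rule, not past the threshold, were the receptor Gpr63 (+1.72, adjusted p 0.246), the kinase Lmtk3 (+3.41) and Fcer1a, a subunit of the IgE receptor (+3.61). Rnf39 (-2.53), Spz1 (-3.02) and Enho, which encodes the metabolic peptide adropin (-1.92 ± 0.35), were lower. Except for Enho, their group means lay below the lowest array median (6.12), and whether those signals were above background is not known. Fcer1a lay at 0 to 0.915 on the untreated arrays. A different probe set of Enho was among the 6 that passed with a variance trend and robust fitting. In this comparison 2016 probe sets (4.48%) had an unadjusted p under 0.05, where chance gives 5%, and groups did not overlap for 9.21%, where chance gives 10%.

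With BI, too, 6 lists passed with the preset correlation and none with the estimated one, and each of the 6 calls was lost without at least 1 of the arrays compared. Cholesterol synthesis was lower in 18 of 20 genes (median -0.51, adjusted p 6.7e-05, and adjusted p = 0.922 with an estimated correlation), with Hsd17b7 at -0.64 ± 0.22 and Dhcr7 at -0.84 ± 0.34. The groups overlapped in the score of this list per array. Untreated replicate 1 (-0.28) lay below BI replicates 1 (-0.13), 2 (-0.08) and 3 (-0.24), and untreated replicates 2 (0.30) and 3 (1.05) lay above them. Lipogenesis was lower in 24 of 28 genes (median -0.27, adjusted p 0.00626, and adjusted p = 0.922 with an estimated correlation), including Pnpla3, a lipase of lipid droplets (-1.30 ± 0.54), and the fatty acid desaturase Fads1 (-0.71 ± 0.34). The lipogenesis score overlapped too, with untreated replicate 1 (-0.23) between BI replicate 1 (-0.25) and BI replicates 2 (-0.07) and 3 (-0.08). Untreated replicates 2 (0.17) and 3 (0.63) lay above the BI arrays. The falls of cholesterol synthesis and lipogenesis rest on the same untreated arrays as those with insulin, so they are not a separate finding. In BI against insulin their medians were -0.015 (camera with the preset correlation, adjusted p 0.713) and -0.053 (0.882). Lipid droplet genes were higher in 12 of 17 cases (median 0.32, adjusted p 0.00626, and adjusted p = 0.922 with an estimated correlation), among them Lpl, which releases fatty acids from lipoproteins (+1.39 ± 0.48), and Fitm1, which aids droplet formation (+0.57 ± 0.20). Fatty acid oxidation and targets of PPARA, the receptor that drives it, were higher in 21 of 30 cases (median 0.08, adjusted p 0.0170, and adjusted p = 0.922 with an estimated correlation), such as the fatty aldehyde dehydrogenase Aldh3a2 (+0.86 ± 0.20) and the acyl-CoA thioesterase Acot1 (+1.23 ± 0.36). Drug and steroid metabolism was higher in 35 of 44 genes (median 0.16, adjusted p 0.00626, and adjusted p = 0.922 with an estimated correlation). Its members Cyp2c39 and Cyp2c38 were the 2 that passed adjusted over the list alone (both 0.0131), against 0 over all probe sets. Proteasome subunits were higher in 27 of 30 cases by a small amount (median 0.12, adjusted p 0.00830, and adjusted p = 0.922 with an estimated correlation), such as Psma5 (+0.36) and Psma2 (+0.32). The scores of lipid droplets, drug metabolism and the proteasome overlapped as well. BI replicate 1 lay below untreated replicate 3 for lipid droplets (0.12 against 0.21) and drug metabolism (-0.11 against 0.03). For the proteasome, BI replicate 2 (-0.12) lay below untreated replicate 1 (0.02). Only for fatty acid oxidation did the BI arrays (0.10 to 0.31) lie above the untreated ones (-0.15 to -0.08).

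In the BI comparison, too, calls were lost when 1 array was left out, in some fits with a smaller median and in others with a median that held. Without untreated replicate 3 the cholesterol median was -0.18 (adjusted p 0.128), that of lipogenesis -0.065 (0.562) and that of the proteasome 0.055 (0.586), while lipid droplets moved to 0.63 and fatty acid oxidation to 0.23. Without untreated replicate 1, lipid droplets (median 0.24, adjusted p 0.197) and fatty acid oxidation (median 0.092, 0.101) lost their calls, and the medians of lipogenesis and drug metabolism became -0.46 and 0.25. Without untreated replicate 2, fatty acid oxidation had a median of 0.047 (adjusted p 0.0881) and drug metabolism 0.051 (0.254). Without BI replicate 1, lipogenesis (median -0.22, adjusted p 0.0954) and the proteasome (median 0.078, 0.346) lost their calls, and the medians of lipid droplets and fatty acid oxidation were 0.59 and 0.13. Without BI replicate 2, whose growth protocol describes rats, 3 lists were called, lipid droplets (median 0.30, adjusted p 0.145), drug metabolism (0.066, 0.302) and fatty acid oxidation (0.12, 0.0643) being lost, and the proteasome median was 0.20. Without BI replicate 3, fatty acid oxidation (median 0.051) and the proteasome (0.084) lost their calls (both adjusted p 0.0959). With the mean of each gene's probe sets the calls of lipogenesis (median -0.22, adjusted p 0.137), fatty acid oxidation (0.098, 0.0626) and the proteasome (0.12, 0.105) ended though their medians stayed close to those above, and that of the proteasome also ended with equal array medians (0.093, 0.0574). The median of fatty acid oxidation was 0.046 with quantile normalization and 0.052 with equal array medians.

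The other 38 lists did not pass with BI (adjusted p 0.0541 to 0.895), and fry called 0 of 44 (smallest adjusted p 0.813). In the growth hormone list (median 0.05, adjusted p 0.872), Moxd1 was the 1 gene past the threshold adjusted over the list alone (0.0255), against 0 over all probe sets, and Hao2, a peroxisomal oxidase, stood at +1.28 ± 0.36. The insulin signalling list had a median of -0.03 (adjusted p 0.663), with Akt1 at -0.52 ± 0.22 and the adaptor Cbl at -0.31 ± 0.16. Among gluconeogenesis genes and FOXO1 targets (median -0.09, adjusted p 0.339) the transaminase Got1 stood at -0.76 ± 0.25 and Ppargc1a at -0.57 ± 0.20. Histone and DNA modifying enzymes had a median of -0.05 over 51 genes (adjusted p 0.363), with the histone methyltransferase Suv39h2 at -1.10 ± 0.51. Hepatocyte markers had a median of 0.0032, a mean of -0.04 and a test that pointed lower (adjusted p 0.663), and those of adipose tissue, beside the lipid droplet genes, a median of 0.38 (adjusted p 0.210), with Adipoq, an adipocyte hormone, at +2.64 ± 1.00. Adipoq lay at 0.45, 1.69 and 4.01 on the untreated arrays, and whether such dim signals were above background is not known.

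BI was compared with insulin directly to see what the modified form changes at the same total insulin. No single gene passed. Ano4 had the smallest p among the named genes (-3.23, adjusted p 0.0643, lower in 3 of 3 BI arrays) and passed in a test of the mean of each gene's probe sets (adjusted p 0.0352), where it was the 1 gene called. Cabp1 (+3.31, adjusted p 0.174), Nxph1 (+3.52), Krtap15, a hair keratin-associated protein (+3.33), Hspa1l, a testis heat shock protein (+2.70), and Ly6h (+2.44) were the higher genes named, and Cdhr2 (-3.42, adjusted p 0.123), Paqr6 (-2.79), Gpr31b (-2.82) and Eomes (-1.85) the lower. The group means of these 10 genes, too, lay below the lowest array median. limma called 0 of 45037 probe sets, and 1821 (4.04%) had an unadjusted p under 0.05, where chance gives 5%. The groups did not overlap for 9.60% of probe sets, where chance gives 10%. The count was 1 when dim probe sets were left out, 1 without insulin replicate 1 and 1 without insulin replicate 2.

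With BI against insulin, 7 lists passed with the preset correlation and none with the estimated one: as lower those of interferon response, MHC class II, Kupffer cells and endothelial cells, and as higher those of lipid droplets, fatty acid oxidation and drug metabolism. The Gapdh 3' minus 5' difference also separated these groups (0.48 to 0.55 on insulin arrays, 0.26 to 0.42 on BI arrays), while that of Actb overlapped (2.00 to 2.23 and 1.96 to 2.09), and whether RNA quality bears on these lists was not tested. Interferon-response genes were lower in 27 of 29 cases (median -0.60, adjusted p 2.3e-05, and adjusted p = 0.866 with an estimated correlation), with Igtp at -0.82 and the antiviral enzyme Oas2 at -2.15. On BI replicate 1, Oas2 (8.05) lay within the range of the insulin arrays (7.04 to 8.49), as did Igtp (12.14, against 11.93 to 12.68). Oas2 stood at 4.68 and 4.54 on BI replicates 2 and 3. Endothelial markers were lower in 20 of 20 cases (median -0.38, adjusted p 6.4e-05, and adjusted p = 0.866 with an estimated correlation), including the sinusoidal lectin Clec4g (-0.55) and the angiopoietin receptor Tek (-0.41). Kupffer cell and macrophage markers were lower in 20 of 21 cases (median -0.34, adjusted p 0.00273, and adjusted p = 0.866 with an estimated correlation), with the lysozymes Lyz2 at -0.50 and Lyz1 at -0.43. MHC class II genes were lower in 8 of 9 cases (median -0.44, adjusted p 0.0221, and adjusted p = 0.866 with an estimated correlation), among them H2-Aa (-0.59) and the invariant chain Cd74 (-0.47). Lipid droplet genes were higher in 15 of 17 cases (median 0.35, adjusted p 2.96e-04, and adjusted p = 0.866 with an estimated correlation), with Fitm1 at +0.55 and the droplet coat protein Plin4 at +1.09. Fatty acid oxidation was higher in 26 of 30 cases (median 0.12, adjusted p 0.00273, and adjusted p = 0.866 with an estimated correlation), including Acot1 (+0.75) and Aldh3a2 (+0.40). Drug and steroid metabolism was higher in 30 of 44 cases (median 0.08, adjusted p 0.0388, and adjusted p = 0.912 with an estimated correlation), with Cyp2c39 at +0.74 and Hsd3b2 at +0.59. The BI and insulin arrays did not overlap in the scores of the endothelial, Kupffer cell and MHC class II lists. They overlapped in those of the other lists called. The 4 lists called lower here did not pass in BI against untreated with the preset correlation. Medians there were 0.11 for interferon response and 0.06 for MHC class II (both adjusted p 0.543). They were -0.12 for endothelial and -0.13 for Kupffer cell markers (both adjusted p 0.363). Interferon, MHC class II and endothelial lists were called higher in insulin against untreated, which uses the same insulin arrays.

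No member of the lists called in BI against insulin passed over all probe sets or adjusted over the list alone. In this comparison fry called 0 of 44 lists (smallest adjusted p 0.748), and the other 37 had adjusted p of 0.101 to 0.993. Without insulin replicate 3, 2 lists were called, with fatty acid oxidation (median 0.087, adjusted p 0.147), lipid droplets (0.31, 0.0750), Kupffer cells (-0.30, 0.0757), MHC class II (-0.28, 0.467) and drug metabolism (0.065, 0.434) lost. Without BI replicate 3, 3 were called. Those lost then were the interferon response (median -0.32, adjusted p 0.0775), Kupffer cells (-0.18, 0.386), MHC class II (-0.52, 0.0525), fatty acid oxidation (0.087, 0.0525) and drug metabolism (0.044, 0.0775). The interferon response was also lost without insulin replicate 2 (median -0.29, 0.0872) and stood at -1.03 without BI replicate 1, which ended the MHC class II call (median -0.41, 0.111) and moved drug metabolism to 0.16. Without BI replicate 2, drug metabolism had a median of 0.029 (0.729) and lipid droplets 0.19 (0.0241). Drug metabolism was also lost with quantile normalization (median 0.051, 0.182), and with the mean of each gene's probe sets both it (0.081, 0.0824) and MHC class II (-0.37, 0.230) were lost.

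Over the 3 groups together the moderated F test of limma called 0 probe sets (smallest adjusted p 0.0723), and 1981 had an unadjusted p under 0.05. It called 1 without insulin replicate 2, 1 when dim probe sets were left out and 3 with the mean of each gene's probe sets. Across 18193 genes, which are not independent replicates, the changes with insulin and with BI against the shared untreated arrays correlated at r = 0.517. Unchanged groups, simulated together with an untreated group that they share, gave r = 0.501. The simulated genes were drawn independently, so this value does not show how widely r spreads when genes vary together. The covariance was 0.205 against a simulated 0.197, a difference of 0.0077, and 68.1% of genes changed with the same sign against a simulated 66.7%. With 3 controls no split into parts of at least 2 arrays was possible, so part of any excess may come from the shared controls.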

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

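The floor at 6, the filter joined with a variance trend and robust fitting, the clock covariate and the test of r against other splits of the arrays were chosen after seeing the data. The 0 probe sets of insulin against untreated stayed 0 in each alternative run. The BI count of 5 was 4 with quantile normalization, 4 with array weights and 6 with variance trend and robust fitting. It was 1 with the dim filter (Hnrnpl), 2 with the mean of a gene's probe sets, 0 with only the 2 groups compared, 0 with a floor at 6, 1 with the dim filter with trend and robust fitting, 0 with the clock score covariate, and 0 to 0 when 1 array of the groups compared was left out. A floor at 6 sets both groups of 3 of the 5 to the floor by its construction. The dim filter, alone or with trend and robust fitting, takes all of the 5 but Hnrnpl out of the test by their level. Fits of fewer arrays have fewer degrees of freedom. The cause of the other changes was not tested. For BI against insulin the count of 0 was 1 with the dim filter, 1 with the gene mean and 0 to 1 on leaving out 1 array. For the F test it was 1 with the dim filter, 3 with the gene mean, 1 with the dim filter with trend and robust fitting and 0 to 1 on leaving out 1 array. Called lists numbered 6, 6 and 7, and 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. Leaving out 1 array gave 4 to 8, 3 to 6 and 2 to 9 lists, and the dim filter gave 13 for BI against insulin, with 40 lists testable. The correlation of effects was 0.541 with the dim filter. It was 0.606 to 0.629 without 1 untreated array and 0.458 to 0.471 without 1 insulin or BI array. Fewer untreated arrays raise the r of unchanged groups and fewer treated arrays lower it. These values can therefore not be set beside the simulated 0.501, and they do not show that r depends on single arrays. Of 68 named values under 1102 alternatives, 1 reversed (H2-DMa with insulin, -0.53 as the mean of its probe sets), 5 came to pass the threshold and 46 lost a call or met the floor. Of 266 values of called lists under alternatives 186 kept the call and 0 reversed. The named values and the called lists were picked by small p in these same data. Few reversals were therefore likely from the start, and their number does not show that the changes are real. With the replicate number as a block, 0, 0 and 0 probe sets and 6, 6 and 6 lists were called, that of drug metabolism in BI against insulin being lost (median 0.081, adjusted p 0.0678). The numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.159 to 0.147 over 9 pairs and those of different numbers at -0.147 to 0.156 over 18. Other pseudocounts do not apply to values deposited as log2. The signal limits what can be seen: the median residual SD was 1.23 at levels of 3 to 5 and 0.14 at 12 to 17.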

Other observations

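The tests of the other probe sets of Hnrnpl and Slc6a14, of the correlation within lists, of single arrays behind list calls, of Dbp with Arntl and of r over regroupings were chosen after the results were seen. The cell cycle, neutrophil and acute phase lists had their highest scores on 1 untreated array. The cell cycle score of untreated replicate 2 was 0.95 and that of the other 8 arrays lay between -0.22 and 0.11. The same array had the highest score of neutrophil markers (0.81) and of acute phase genes (0.58), the secreted liver proteins of inflammation. Cell cycle genes were lower with BI than without treatment in 24 of 35 cases (median -0.18) but did not pass (adjusted p 0.0541), with the cyclin Ccna2 at -1.56 ± 0.49 and the replication factor Cdc6 at -3.01 ± 1.26. Among genes of bile acids and sterol transport with BI (median 0.09, adjusted p 0.437), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -1.41 ± 0.40 and the sterol exporter Abcg8 at +0.82 ± 0.44. The small heat shock protein Hspb1 stood at +0.78 ± 0.21 with BI (adjusted p 0.855), and Cxcl2, a chemokine that draws neutrophils, at -1.35 ± 0.44 with insulin and -1.42 ± 0.44 with BI.

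Clock genes differed widely within groups. Dbp, a transcription factor and direct clock output, ranged from 7.28 to 11.77 over the 9 arrays. Of 17 clock genes set against it, 5 had an adjusted p under 0.05 by exact permutation: Per3 (r = 0.912), Tef (0.901) and Nr1d2 (0.880) were positive, and Arntl (-0.907), the core activator, and Npas2 (-0.866) negative, each with an adjusted p of 0.00765. Spearman's rho was 0.767 for Per3 (exact p 0.0214), 0.733 for Tef (0.0311), 0.900 for Nr1d2 (0.00203), -0.867 for Arntl (0.00451) and -0.833 for Npas2 (0.00827). Adjusted over the 17 genes, these rank correlations did not pass for Per3 (adjusted p 0.0519) and Tef (0.0588), passed for Nr1d2 (0.0172), Arntl (0.0255) and Npas2 (0.0351), and passed also for Cry1 (rho -0.800, adjusted p 0.0470) and Nfil3 (-0.900, 0.0172), which did not pass by r (-0.718, adjusted p 0.0634, and -0.735, 0.0622). Without insulin replicate 1 and BI replicate 2, the arrays farthest from the median of Dbp, r was 0.904 for Per3, 0.859 for Tef, 0.885 for Nr1d2, -0.796 for Arntl and -0.665 for Npas2. With BI against untreated the clock list did not pass (median -0.20, adjusted p 0.680).

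An array-wide scaling difference would move Dbp and Arntl one way, and their r of -0.907 argues against it as the whole account of the clock spread. A difference of RNA quality need not move both genes one way, so this r does not decide about it. Whether RNA quality bears on the clock spread was not tested. A candidate explanation is that the animals were sampled at different clock phases. Wee1, a clock-controlled kinase outside the list, correlated with Dbp at r = 0.550, but with an exact p of 0.123, a rho of 0.05 (exact p 0.912) and r = 0.318 without the 2 farthest arrays. That r lies above a bound of 0.5 set before it was seen, but the bound ignored the error of an r over 9 arrays, and after the values were seen a permutation p under 0.05 was required too. Phase therefore stays open, as the labels used here give no time of sampling.

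The called probe sets may or may not stand for whole genes. For Hnrnpl the brighter probe set was at -0.042, with an interval above that of the called one. This argues against a change of all transcripts if the brighter probe set reads all of them, which was not checked. A hypothesis is that the called probe set reads a part of the transcripts or another sequence. Chance is not excluded for this call either. For Slc6a14 the other probe set, at -0.53, lies below the interval of the called one (3.39 to 4.88). This met the bound written for excluding a change of the gene, but that probe set is dim itself (35.4th percentile of levels), so after the values were seen the question was left open.

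The list calls may reflect genes that vary together between arrays of one group rather than the treatments. The correlation estimated within groups had a median of 0.361 over the 11 lists called (0.123 to 0.640), against the preset 0.01, which is consistent with such shared variation. Of the 19 list calls, 3 stayed under 0.05 in every fit that left out 1 array of the groups compared. In 12 others the call was lost in a fit where the median also fell by more than 1.5 times, which is consistent with single arrays setting those calls. In the other 4 the median fell by less or not at all in each such fit, as it did in 16 of all 34 fits that lost a call, so those losses do not show that 1 array set the call, and fewer arrays also give a weaker test. A response to the treatments that differs between animals was not tested.

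Other splits of the same arrays were run for each count. Splits of 3 against 3 arrays number 10, too few for a share under 0.05. For BI against untreated the real split called 5 probe sets, a count reached by 1 of 10 splits, the real one, and the highest other called 1. For insulin against untreated the real split called 0, a count that any split reaches (10 of 10). The highest other there, untreated replicate 1 with insulin replicates 2 and 3 against the rest, called 20. A count so far above the real one points to a possible structure of the samples, but the split was picked as the highest of the 9 others, and how high such a count goes in samples without structure was not tested. For BI against insulin the real split called 0, which any split reaches too (10 of 10), and the highest other 9. Lists called in the real split and in the highest other were 6 and 15 for insulin (5 of 10 as large), 6 and 16 for BI (7 of 10) and 7 and 10 for BI against insulin (2 of 10). For the F test the real count was again 0, so that 100 of 100 drawn splits of the 9 arrays reach it whatever the data hold (highest other 7), and this count decides nothing about chance. The correlation of the insulin and BI effects, 0.517, was reached by 19 of 100 regroupings (highest other 0.554), and chance is not excluded for it.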
